A study of Homo sapiens with 9 samples.

How the data were processed

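The series holds RNA sequencing of 9 libraries from human tumour-infiltrating CD8 T cells in 3 groups of 3. Per the labels' protocols, leukocytes from non-small cell lung cancers were stained for CD45, CD8, CCR7, CD45RO and CD45RA and sorted into the Ebo, Em and Eff subsets. Fewer Eff than Em cells went into each library, and RNA was extracted with a kit for small samples. The molecule sequenced was polyA RNA, per the labels. The sort gates, the library kit, the read length and whether strand was kept are not given in the sources used here.

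The deposited files hold whole-number counts per Ensembl gene, 1 file per library with 58288 features each, per the file contents. The submitters' processing notes name the build hg38 and the tools HISAT2, StringTie, DESeq and DESeq2, with no roles, order or versions, so how the authors made the counts from the alignments is not known here. The counts are not normalized: library totals differ, and no file carries a scaling factor. Where reads from paralogs or overlapping genes went depends on that unrecorded counting step.

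Gene names, types and coordinates came from GENCODE release 29 on GRCh38. Of the features, 55661 matched an identifier with the same version and 57980 matched without the version. A set of 564 features on the Y chromosome, with XIST and TSIX, was left out of all totals and tests, because the donors are patients. A count above 0 in any library was found for 24091 features.

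Groups came from the sample titles. Each title also carries a prefix shared by exactly 1 library of each group, and that prefix was read as the donor. The pairing was checked before fits were compared, through each library's deviations from its group mean log2 CPM. Same-donor libraries of different groups correlated at 0.0342 to 0.188 over 9 pairs, and libraries of different donors at -0.126 to -0.00887 over 18 pairs. In 18 of 18 matches of a library to another group, the best correlated library came from the same donor. The values over genes are not independent replicates.

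The following choices were made before the data were examined, apart from the alternatives named below as added. Genes were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood fit with robust moderation, TMM factors and the filterByExpr filter, which left 14794 genes. All 9 libraries entered 1 model without a donor term, with 6 residual degrees of freedom. The design gave no control group, so each pair of subsets was compared, two-sided, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. The common dispersion was 1.64, a biological coefficient of variation of 1.28. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. CPM values are counts scaled to the TMM-adjusted library size, given as mean ± SD over 3 libraries. A fold against a group with 0 counts in all libraries is given as a lower bound, with 3 counts assigned to each library of that group. Such bounds cover counting error only, and reads without molecular identifiers are not independent molecules.

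Of 38 gene lists fixed in advance, 34 had at least 4 tested members and were tested with camera from limma 3.58.1, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. Adjustment ran over the lists of a kind and the 3 comparisons together. The kinds were 23 lists of T-cell states and processes, 3 of RNA quality, 7 of other cell types and 1 of the sorting antigens. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, in 1 direction, and does not compare them with other genes. Members passing a test are counted over all genes tested and adjusted over the list alone.

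Genes named in the text followed a rule fixed in advance. Per comparison it took up to 8 called genes in each direction with a mean log2 CPM above 2 and the same sign in all 3 donors. Where none passed, it took the 5 with the smallest p in each direction, for their values. It added up to 3 called members of each state list, or the member with the smallest p, a fixed set of T-cell genes with the sorting antigens, and 2 members of each passing list of another cell type or of RNA quality. Receptor variable segments, unnamed features and small RNA genes were never named. Any gene named outside that rule is marked as chosen after its values were seen.

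Totals, genes detected and shares of counts were compared by two-sided exact permutation tests. With 3 libraries against 3 the smallest p such a test allows is 0.1. Alternatives fixed in advance were a donor block with 4 residual degrees of freedom, RLE and upper-quartile factors, DESeq2 1.42.0 with and without the block, and limma-voom with sample quality weights. They also covered no low-count filter, a mean CPM of at least 10, the 2 groups compared alone, an adjusted p under 0.1, a fold of at least 2, a fit without robust moderation, and removal of mitochondrial, immunoglobulin and haemoglobin genes. Each library and each donor was left out in turn. Alternatives planned for FPKM values were not run, because the files hold counts. Added after the data were examined were thinning of every library to the smallest total, list tests without each donor, the block with an estimated correlation, and the 2 groups alone with the block.

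The code was tested on simulated data drawn from the real means and library sizes, with 200 changed genes. For Ebo versus Em, edgeR recovered 2 of 67 genes changed 4-fold, 22 of 67 changed 16-fold and 28 of 66 changed 64-fold, with 3 false calls among 13274 genes. For Ebo versus Eff it recovered 4, 17 and 27 with 2 false calls among 13360 genes, and for Eff versus Em 2, 16 and 17 with 1 false call among 13287 genes. In 20 simulations of unchanged groups over 14794 genes, edgeR called a mean of 0.117 genes per comparison and at most 1. DESeq2 was run on 3 of these simulations and called up to 173 genes and, with the block, up to 458. The counts were drawn with the dispersions edgeR had estimated and with no donor effect, a setting that can favour edgeR. DESeq2 counts are given as alternatives only, as fixed in advance. A 4-fold change of the cell cycle list was recovered in each of the 3 comparisons, with 0 other lists called. Simulated genes were drawn independently of each other, so this cannot show how often lists whose genes vary together are called falsely. In the real data the estimated correlation for Ebo versus Em was 0.157 in the cell cycle list and 0.84 in the ribosomal protein list.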

Results

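RNA sequencing profiled 3 subsets of CD8 T cells, labelled Ebo, Em and Eff, that had been sorted from the leukocytes infiltrating human non-small cell lung cancers. The series title concerns a CD8 T-cell population described as burned out, and the labels do not spell out the abbreviations. Each subset had 3 libraries, 1 from each of 3 donors as read from the titles. Total counts were 19932122, 11760162 and 83930783 in the Ebo libraries of donors 1, 2 and 3. The Em libraries held 14089814, 11736327 and 58292156 counts, and the Eff libraries 9321051, 7752525 and 33834362. Each gene's count per library was compared between subsets against the spread between libraries of a subset. Gene p-values therefore describe the spread between libraries from these 3 donors, with donor and technical spread mixed. Camera p-values at the preset correlation take genes as nearly independent and do not measure variation among donors.

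Fewer genes were detected in Eff than in the other subsets. At least 1 count was found for 16934 ± 1167 genes in Ebo, 15878 ± 2900 in Em and 11147 ± 1065 in Eff (mean ± SD, n = 3 each). Every Eff library lay below every Ebo and every Em library, and 1 Em library, that of donor 3, lay near them at 12577. The exact permutation p for Ebo against Eff was 0.1, the smallest that 3 against 3 allows, and 66 such composition tests were run, with a lowest adjusted p of 0.33. All mitochondrially encoded genes together took 9.01% to 10.1% of counts in Ebo, 10.9% to 23.6% in Em and 10.6% to 23.2% in Eff. The 13 of them in the list tested below took 4.47% to 5.47%, 4.88% to 12.5% and 4.86% to 10.2%, so that the subsets overlapped.

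**Figure D1:**
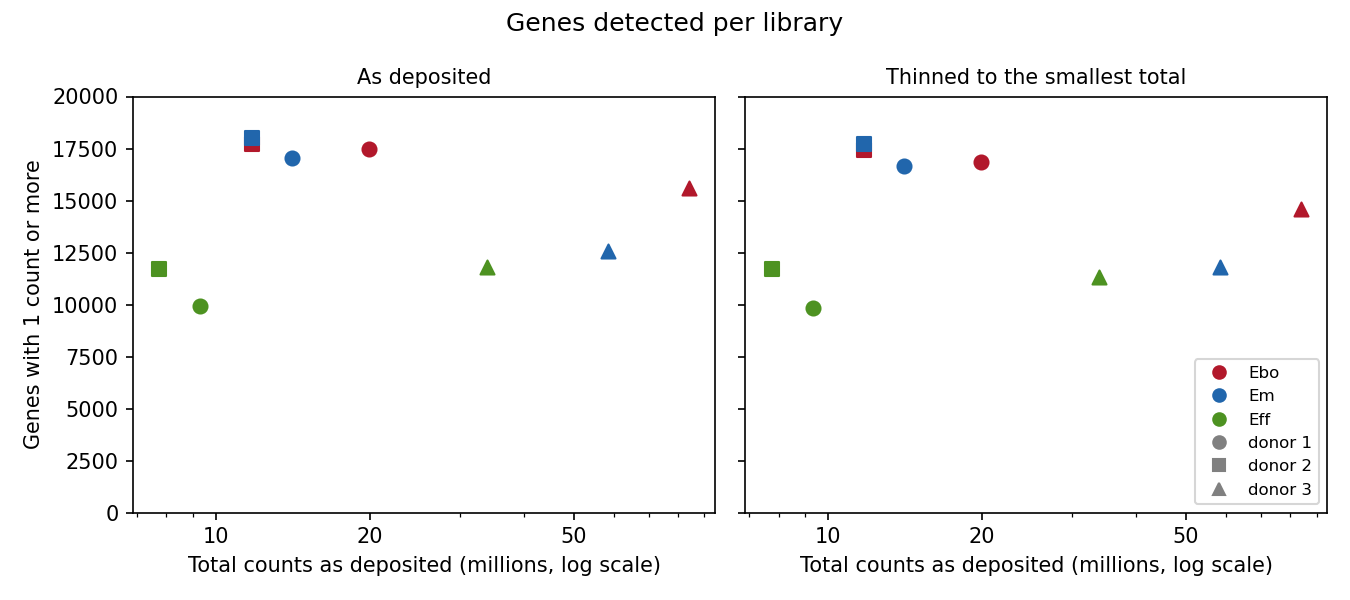
Genes with at least 1 count (vertical axis) against deposited total counts (log axis) for the 9 libraries, with genes counted as deposited on the left and after thinning of every library to the smallest total on the right. Colours mark subsets and shapes donors. The Eff libraries hold 9919 to 11817 genes as deposited and the Ebo libraries 15593 to 17722.

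The antigens used for sorting were measured in every subset. CD8A stood at 932 ± 103 CPM in Ebo, 861 ± 93.6 in Em and 565 ± 88.1 in Eff, and CD8B, the partner chain of the CD8 co-receptor, at 150.01 ± 42.3, 188 ± 79.6 and 94.6 ± 46.3 CPM. PTPRC, the gene of CD45 and its RA and RO forms, had 2429.9 ± 406, 2123 ± 331 and 2523 ± 695 CPM. CCR7, a lymph-node homing receptor, had 59 ± 29.02, 76.2 ± 55.4 and 55.8 ± 36.1 CPM. None of the 4 genes passed the edgeR test over all genes in any comparison, and the list did not pass either (adjusted p = 0.866 in each of the 3 comparisons). Adjusted over the list alone, 1 gene passed for Ebo versus Eff, higher in Ebo. CD8A was lower in every Eff library (486 to 660 CPM) than in any Ebo (825 to 1031) or Em library (762 to 948). Gene counts do not separate the RA and RO forms of CD45.

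The first comparison asked how Ebo cells differed from Em cells. Ebo libraries held more transcript of cell division genes. All 40 members of the cell cycle list had a higher fitted level in Ebo, 35 of them in all 3 donors. For a single gene, chance gives 12.5% per direction. Members vary together (estimated correlation 0.157), so their number does not add to the 3 donors. The list's median log2 fold change was 2.32 (camera adjusted p = 1.49e-39, and adjusted p = 0.0677 with an estimated correlation), and fry gave an adjusted p of 0.0126. MKI67, a marker of cycling cells on chromosome 10 (128096659 to 128126385), had 559 ± 433 CPM in Ebo and 66.2 ± 18.9 in Em, with a log2 fold change of 3.08 ± 0.78 (SE). CENPF, a kinetochore protein gene on chromosome 1 (214603195 to 214664588), had 280.2 ± 90 and 45.3 ± 17.4 CPM. In edgeR neither of these 2 genes passed over all genes tested (adjusted p = 1.000 for both), and 1 member of the list passed when adjusted over the list alone. DESeq2 called 6 members over all genes, and limma-voom called 3, CENPF among them.

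At the level of single genes, edgeR called 0 of 14794 genes between Ebo and Em, with 222 genes at an unadjusted p under 0.05 where 739.7 are expected by chance. With the 2 groups compared alone it was 402 of 14461 genes, and by limma-voom 754 of 14794. The count below chance is therefore no sign that the subsets are alike. In the main edgeR fit, the genes with the smallest p in Ebo's favour, besides MKI67 and CENPF, were GZMK, HIST1H2AJ and SYNE1. GZMK, a granzyme of memory-like CD8 T cells, had 382 ± 123 CPM in Ebo and 99.3 ± 52.98 in Em. SYNE1, a nuclear envelope protein gene, had 1186 ± 97.1 and 544 ± 158 CPM, and the histone gene HIST1H2AJ 108 ± 77.2 and 20.2 ± 3.08. On the Em side stood IRS2, an adaptor of insulin signalling, with 52.8 ± 18.5 CPM in Ebo and 224 ± 119 in Em, and IGF1R, the IGF1 receptor gene, with 0.0565 ± 0.0978 and 15.4 ± 7.97 CPM. The inhibitory receptor gene LILRB1 had 0.0754 ± 0.131 and 16.6 ± 9.11 CPM, the chromatin remodeller gene CHD7 33.9 ± 8.03 and 114 ± 47.4, and the glycosyltransferase gene MGAT5 81.1 ± 18.6 and 176 ± 38.7. With other tools the count of called genes was 116 by DESeq2, 553 by DESeq2 with a donor block and 10 by limma-voom.

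Lists of T-cell states divided between the 2 subsets. NF-kB and immediate-early genes, which respond within minutes to stimulation, stood slightly lower in Ebo, with 22 of 26 members lower and a median of -0.21 (camera adjusted p = 0.0421, and adjusted p = 0.986 with an estimated correlation). FOS had 431 ± 60.1 CPM in Ebo and 656 ± 288 in Em. The circulating terminal effector list stood higher in Ebo by a median of 1.40 over 9 members (adjusted p = 0.0101, and adjusted p = 0.483 with an estimated correlation). Its leading member PLEK, a platelet and leukocyte signalling protein gene, had 100.1 ± 54.3 and 27.7 ± 8.58 CPM. The call on the NF-kB list was lost without Ebo replicate 1, with the direction reversed (adjusted p = 0.834), and without Em replicate 2 or 3 or any 1 Eff library. It was also lost whichever donor was left out (adjusted p up to 0.331). The call on the terminal effector list was lost without Ebo replicate 2, Em replicate 1 or Em replicate 3 (adjusted p up to 0.0869). The inhibitory receptor list did not pass (median -0.04, adjusted p = 0.989), nor did the exhaustion-associated transcription factor list (median 0.27, adjusted p = 0.0777).

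Among the T-cell genes named by the rule, some were higher in Ebo than in Em in every donor, and others were lower or differed in sign between donors. Of the inhibitory receptor list 2 of 13 members were higher in Ebo in all 3 donors and 2 lower. Of the exhaustion-associated list 8 of 15 were higher and 1 lower. The chemokine gene CXCL13 had 179.97 ± 90.97 CPM in Ebo and 48.9 ± 24.1 in Em, with no overlap between the libraries of the 2 subsets (log2 fold change 1.88 ± 0.59, unadjusted p = 0.0123). It was higher in Ebo in all 3 donors, as were TIGIT, TOX, EOMES and CD28, while the sign differed between donors for HAVCR2, ENTPD1, CTLA4, LAG3 and PDCD1. HAVCR2 had 87.96 ± 58.8 CPM in Ebo and 94.1 ± 36.4 in Em, ENTPD1 121 ± 81.9 and 121 ± 28.9, CTLA4 86.2 ± 29.8 and 96.4 ± 59.8, and LAG3 165 ± 80.4 and 132 ± 38.98. PDCD1, the gene of PD-1, had 78.5 ± 31.6 and 45.1 ± 18.02 CPM, TIGIT 104 ± 37.5 and 57.2 ± 12, and TOX, a transcription factor of exhausted T cells, 156 ± 97.7 and 78.4 ± 45.9. EOMES had 168 ± 23.3 CPM in Ebo and 53.1 ± 34.4 in Em, and the costimulatory receptor gene CD28 173 ± 101 and 46.3 ± 29.6. IL7R, the interleukin-7 receptor gene of memory cells, had 769 ± 291 and 1583 ± 609 CPM and lay lower in Ebo in all 3 donors. Cytotoxicity genes gave 269.6 ± 222 and 260.1 ± 114 CPM for GZMB, and 363 ± 193 and 272 ± 92.4 for IFNG. For the survival gene BCL2 the values were 102 ± 45.3 and 142 ± 55.5 CPM. None of these genes passed the edgeR test.

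Lists of other cell types and of RNA quality also differed between Ebo and Em. Natural killer cell markers, several of which CD8 T cells also express, were lower in Ebo for all 13 tested members, 9 of them in all 3 donors (median -2.09, camera adjusted p = 4.81e-13, and adjusted p = 0.117 with an estimated correlation). That list shares KLRF1, KLRC1 and TYROBP with other lists. Its member KIR2DL4 had 1.93 ± 1.97 CPM in Ebo and 26.9 ± 8.41 in Em. Monocyte and macrophage markers were lower in Ebo by a median of -1.79 (adjusted p = 8.10e-04, and adjusted p = 0.412 with an estimated correlation), with S100A9 at 0.282 ± 0.489 and 6.55 ± 4.73 CPM and SPI1 at 0.145 ± 0.250 and 6.08 ± 9.10. Without Em replicate 1 or Ebo replicate 1 the monocyte list did not pass (adjusted p up to 0.781), and without donor 1 its direction was reversed (adjusted p = 0.785). Mitochondrially encoded genes had a lower fitted level in Ebo for all 13 members, 6 of them in all 3 donors, while in donor 2 the list mean was slightly higher in Ebo (median -1.09, adjusted p = 1.02e-16, and adjusted p = 0.197 with an estimated correlation), with MT-CYB at 2981 ± 485 and 7092 ± 3227 CPM and MT-ND5 at 6341 ± 1006 and 13457 ± 5962. With a donor block the ribosomal protein list also stood lower in Ebo (adjusted p = 0.00875, against 0.0829 without it), but not with the block and an estimated correlation (adjusted p = 0.248).

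**Figure D2:**
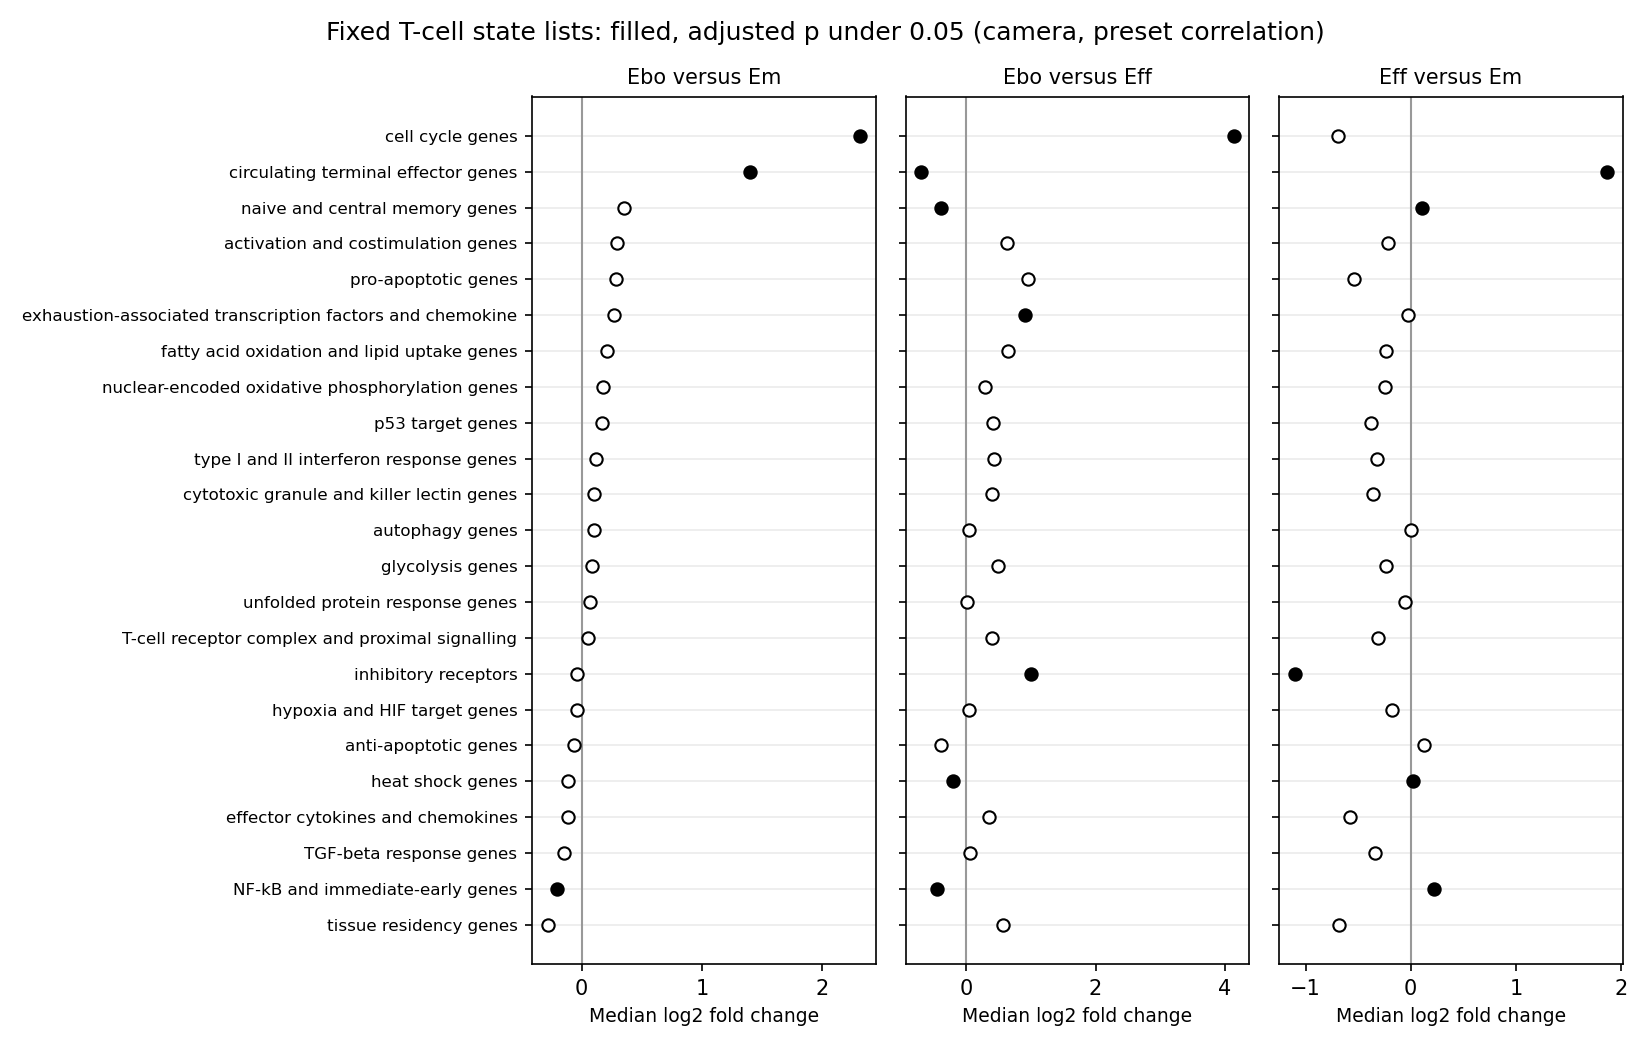
Median log2 fold change of each T-cell state list in the 3 comparisons, with genes absent from a whole group placed at their bound. Filled points passed the list test at the preset correlation, among them the cell cycle list at 2.32 for Ebo versus Em and 4.14 for Ebo versus Eff.

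The second comparison set Ebo against Eff. CXCL13, a chemokine that attracts B cells and is made by tumour-reactive CD8 T cells, was higher in Ebo and was the only gene edgeR called. It lies on chromosome 4 (77511753 to 77611834, ENSG00000156234.7) and had 179.97 ± 90.97 CPM in Ebo and 0 counts in all 3 Eff libraries, a level at least 685-fold higher in Ebo (adjusted p = 0.0135). That bound covers counting error only, and 1313 of 13259 genes detected in every Ebo library were missing from all 3 Eff libraries. Counts of 0 in Eff, here and below, therefore need not mean that a gene is silent. With the donor block the call was lost (adjusted p = 0.107), leaving 0 genes. A further 1612 genes higher and 160 lower in Ebo, CXCL13 counted among the higher, had an unadjusted p under 0.05, where 739.7 in all are expected by chance. DESeq2 called 1363 genes, DESeq2 with the block 2957 and limma-voom 0. Leaving out 1 Eff library raised edgeR's count to 37, 137 and 90 for replicates 1, 2 and 3, and leaving out Ebo replicate 2 gave 2.

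Cell cycle genes stood higher in Ebo than in Eff as well, beside the lower number of genes detected in Eff. Of 40 members 39 had a higher fitted level in Ebo, 33 of them in all 3 donors, and 24 passed in edgeR when adjusted over the list alone while 0 passed over all genes. Over all genes DESeq2 called 22 members, 26 with the donor block, and edgeR called 3 to 6 without 1 Eff library. The median log2 fold change was 6.66, or 4.14 with the members absent from a group at their bound (camera adjusted p = 2.08e-20, adjusted p = 0.185 with an estimated correlation, and fry adjusted p = 0.00566). MCM2, a helicase gene of DNA replication, had 49.1 ± 29.6 CPM in Ebo and 0 counts in Eff, at least 187-fold higher in Ebo (adjusted p = 0.0511). MKI67 had 35.8 ± 26.2 CPM in Eff and CENPF 30.2 ± 11.4, against the Ebo levels given above.

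Inhibitory receptor genes were higher in Ebo than in Eff for 11 of 13 members, with a median log2 fold change of 1.01 (camera adjusted p = 0.0306, adjusted p = 0.483 with an estimated correlation, and fry adjusted p = 0.0345). PDCD1 had 5.47 ± 4.47 CPM in Eff, a log2 fold change of 3.83 ± 0.75 (adjusted p = 0.169). CTLA4 had 18.6 ± 16.2, ENTPD1 28.4 ± 32.8, LAG3 66.1 ± 22.7, HAVCR2 43.8 ± 45.8 and TIGIT 72.2 ± 28.8 CPM in Eff. The exhaustion-associated list, which holds CXCL13, had a median of 0.90 with 10 of 15 members higher in Ebo (camera adjusted p = 0.0306, adjusted p = 0.354 with an estimated correlation, and fry adjusted p = 0.00566). TOX had 94.7 ± 64.4 CPM and EOMES 48.6 ± 17.9 CPM in Eff. With the donor block neither list passed (adjusted p = 0.0505 and 0.151), and without Eff replicate 3 or Ebo replicate 3 neither passed (adjusted p up to 0.201 and 0.166). The first was also lost without Ebo replicate 1, and the second without Ebo replicate 2, Em replicate 2, Em replicate 3 or Eff replicate 2. With each of the 3 donors left out in turn, the first list held in 1 case and the second in 0. Without donor 3 the adjusted p was 0.661 and 0.539. Most genes with an unadjusted p under 0.05 were higher in Ebo (1612, against 160 lower). Fry does not compare a list with other genes, so its p can reflect that shift. Neither list was checked against lists matched on mean expression, so a general loss of transcripts in Eff stays open for both.

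Other T-cell programmes had a lower median in Ebo than in Eff. Camera compares a list with all other genes, and most genes with an unadjusted p under 0.05 were higher in Ebo. Here and below, a list can therefore pass as lower in Ebo with little change of its own. NF-kB and immediate-early genes were lower in Ebo for 22 of 26 members (median -0.45, camera adjusted p = 1.46e-06, and adjusted p = 0.545 with an estimated correlation), with FOS at 752 ± 184 CPM in Eff. The naive and central memory list had a median of -0.40 but a mean of 0.23, so that the sign differs between them (adjusted p = 0.00203, and adjusted p = 0.400 with an estimated correlation). Its member TCF7, a transcription factor gene of stem-like T cells, had 157 ± 69.5 CPM in Ebo and 337 ± 95.8 in Eff, while CD28 had 42.7 ± 13.8 CPM in Eff. All 9 tested circulating terminal effector genes had a lower fitted level in Ebo (median -0.70, adjusted p = 0.00203, and adjusted p = 0.416 with an estimated correlation). Heat shock genes were lower by a median of -0.20 (adjusted p = 0.00917, and adjusted p = 0.986 with an estimated correlation). The naive and central memory call was lost without Eff replicate 3 (adjusted p = 0.0587) and the terminal effector call without Eff replicate 2 (adjusted p = 0.121). The heat shock call was lost without Ebo replicate 1, Eff replicate 2 or Eff replicate 3 (adjusted p up to 0.743).

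Single genes of the remaining programmes are given for their levels, since edgeR called none of them. GZMK had 288 ± 160.4 CPM in Eff, GZMB 123 ± 118, GZMA 379.6 ± 156 in Ebo and 133 ± 59.1 in Eff, and IFNG 173 ± 78.5 in Eff. ICOS, a costimulatory receptor gene, had 152 ± 25.6 CPM in Ebo and 26.9 ± 7.49 in Eff, and CXCR6, a chemokine receptor gene of tissue-resident cells, 91.3 ± 44.99 and 20.5 ± 11.2. IL7R had 1180.5 ± 513 CPM in Eff and BCL2 133 ± 23.9. The pro-apoptotic and interferon response lists passed fry (adjusted p = 0.0396 and 0.0290) and not camera (adjusted p = 0.464 and 0.989). Since fry does not compare a list with other genes, these passes can reflect the general excess of genes higher in Ebo. Lower in Ebo with the smallest p were SNHG5, a host gene of small nucleolar RNAs, at 73.9 ± 19.2 CPM in Ebo and 183 ± 11.8 in Eff, and CHKB-CPT1B, a read-through transcript whose reads its neighbours can share, at 7.66 ± 2.67 and 86.3 ± 6.11. GSE1 had 54.8 ± 2.96 and 169 ± 74.9 CPM, IGF1R 27.2 ± 14.7 in Eff and LILRB1 21.8 ± 8.11 in Eff.

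Markers of B cells, plasma cells and natural killer cells had higher mean levels in Eff than in Ebo. By mean log2 CPM, none of these 3 lists moved the same way in all donors. By share of counts, plasma cell and natural killer markers were higher in Eff than in Ebo in all 3 donors. Natural killer markers took 0.00702% in Ebo and 0.0275% in Eff on average, without overlap (exact permutation p = 0.1, adjusted p = 0.33). B cell markers had a lower fitted level in Ebo for all 8 tested members, with a median of -8.65, or -6.67 with absent genes at their bound (camera adjusted p = 1.31e-06, and adjusted p = 0.286 with an estimated correlation). MS4A1, the gene of CD20, had 4.55 ± 5.90 CPM in Ebo and 63.95 ± 68.4 in Eff, and BANK1, a B cell adaptor gene, 0.0847 ± 0.147 and 112 ± 169.7, with an SD in Eff as large as the mean. In donor 1 the mean log2 CPM of the B cell and of the plasma cell markers was lower in Eff than in Ebo. Only 2 of 8 B cell and 1 of 8 plasma cell members were lower in Ebo in all 3 donors. Plasma cell markers had a median of -3.60 (adjusted p = 2.64e-04, and adjusted p = 0.286 with an estimated correlation), with IGHM at 7.53 ± 7.65 and 168 ± 144 CPM and JCHAIN at 0.0847 ± 0.147 and 42.9 ± 69.4. Natural killer markers had a median of -2.38 (adjusted p = 1.75e-06, and adjusted p = 0.286 with an estimated correlation), with SPON2 at 8.53 ± 5.48 and 44.4 ± 4.75 CPM, and that call was lost without donor 2 (adjusted p = 0.109). Of its 13 members 4 were lower in Ebo in all 3 donors, and in donor 3 the mean log2 CPM of the list was lower in Eff than in Ebo. Ribosomal protein genes were lower in Ebo by a median of -0.30 over 70 genes (adjusted p = 5.93e-13, adjusted p = 0.458 with an estimated correlation and 0.0323 with the donor block besides), RPL5 standing at 781 ± 188 and 1228 ± 142 CPM and RPL15 at 138 ± 20.01 and 295 ± 180.2. Mitochondrially encoded genes were lower by a median of -0.88 (adjusted p = 1.45e-07, and adjusted p = 0.226 with an estimated correlation), with MT-ATP8 at 1023 ± 174 and 2289 ± 754 CPM and MT-ND4L at 949 ± 101 and 1952 ± 560.4. The mean log2 CPM of that list went the other way, at 11.03 in Ebo and 10.66 in Eff, and in donor 1, whose Eff library had few or no counts of 3 of the genes, it was higher in Ebo. Nuclear-retained long non-coding RNAs had a median of -0.05 and a mean of 0.83, with opposite signs (adjusted p = 0.0264, and adjusted p = 0.226 with an estimated correlation), and that call was lost without Ebo replicate 1, Ebo replicate 3 or Eff replicate 2 (adjusted p up to 0.0702).

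**Figure D3:**
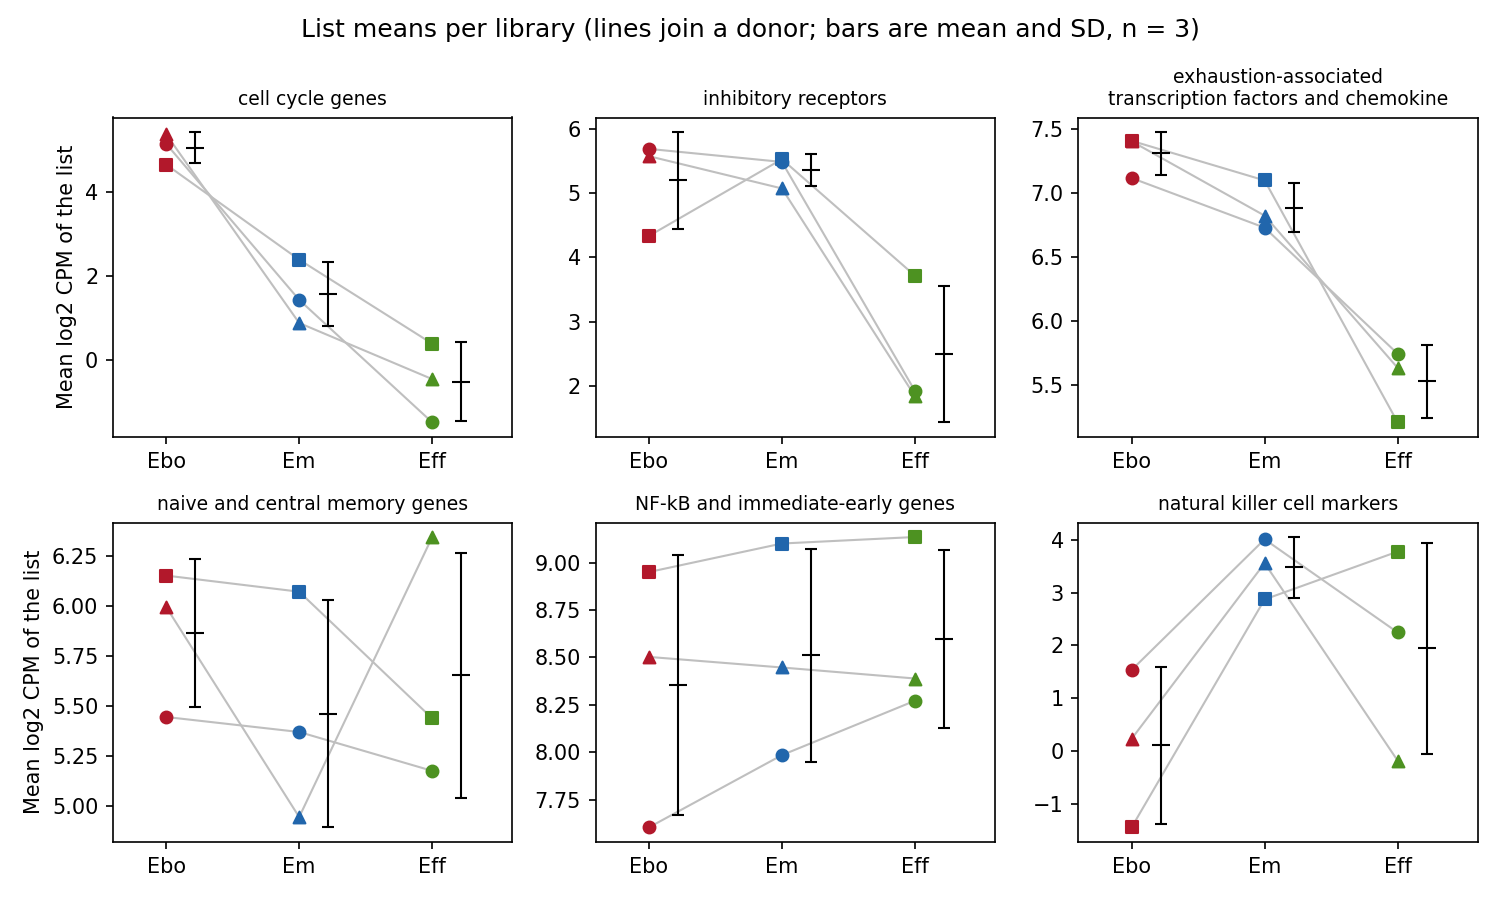
Mean log2 CPM over the members of 6 lists in each library, with grey lines joining a donor and bars for the mean and SD of each subset (n = 3). The 3 Ebo libraries have the highest cell cycle values and the 3 Eff libraries the lowest inhibitory receptor values.

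The third comparison set Eff against Em. CXCL13 was lower in Eff and was again the only gene edgeR called, with 0 counts in Eff and 48.9 ± 24.1 CPM in Em, at least 186-fold lower in Eff (adjusted p = 0.0338). With the donor block CXCL13 was not called (adjusted p = 0.214) and MYO7A was (adjusted p = 0.0302), an unconventional myosin gene chosen after its values were seen, with 512 ± 206 CPM in Em, 393 ± 233 in Ebo and 33.4 ± 14.4 in Eff. An unadjusted p under 0.05 was found for 163 genes higher and 1453 lower in Eff. Camera compares a list with all other genes, so a list can pass as higher in Eff with little change of its own. Fry makes no such comparison, so its p can reflect the general shift. No list was checked against lists matched on mean expression in this comparison. DESeq2 called 1174 genes, DESeq2 with the block 2506 and limma-voom 0. Without Eff replicates 1, 2 and 3 edgeR called 30, 103 and 72 genes and without Ebo replicate 2 it called 2, while without Ebo replicate 1, Ebo replicate 3 or any 1 Em library it called 0.

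Inhibitory receptor genes were lower in Eff than in Em for 12 of 13 members, 9 of them in all 3 donors (median -1.10, camera adjusted p = 0.00917, adjusted p = 0.400 with an estimated correlation, and fry adjusted p = 0.0311). PDCD1 had a log2 fold change of -3.03 ± 0.73 (adjusted p = 0.213). Without Eff replicate 3 the list did not pass (adjusted p = 0.110), nor without donor 3 (adjusted p = 0.413). The exhaustion-associated list passed fry (adjusted p = 0.0126) but not camera (median -0.02, adjusted p = 0.236), and so did interferon response genes (fry adjusted p = 0.0415, camera adjusted p = 0.989). Circulating terminal effector genes were higher in Eff for all 9 tested members (median 1.87, adjusted p = 7.72e-07, and adjusted p = 0.267 with an estimated correlation). CX3CR1, a chemokine receptor gene of circulating effector cells, had 12.6 ± 9.37 CPM in Eff and 0 counts in Em, at least 71.3-fold higher in Eff by group mean. The Eff libraries of donors 1, 2 and 3 had 16.98, 18.94 and 1.82 CPM of CX3CR1, and edgeR did not call it. Naive and central memory genes had a median of 0.11 (adjusted p = 1.22e-04, and adjusted p = 0.354 with an estimated correlation), with KLF3 at 161 ± 32.9 CPM in Eff and 39.9 ± 15.6 in Em and TCF7 at 122 ± 55.7 in Em. NF-kB and immediate-early genes had a median of 0.22 (adjusted p = 0.00144, and adjusted p = 0.977 with an estimated correlation), a call lost without Em replicate 1 or Eff replicate 2 (adjusted p up to 0.198).

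Tissue residency genes had a lower fitted level in Eff for 13 of 14 members, but the list did not pass (median -0.68, adjusted p = 0.112). ITGAE, the gene of the CD103 integrin chain, had 537 ± 116 CPM in Em, 353 ± 133 in Ebo and 129 ± 52.3 in Eff. The cell cycle list did not pass between Eff and Em (median -0.69 with absent genes at their bound, adjusted p = 0.0604). Among the genes with the smallest p on the Eff side were CD37, a leukocyte tetraspanin gene, at 300.1 ± 47.4 CPM in Eff and 90.7 ± 10.4 in Em, SYNE1 at 1303 ± 235 in Eff, and the peptidase gene TPP2 at 243 ± 19.5 and 118 ± 17.2. HK2, a hexokinase gene of glycolysis, had 0 counts in Eff and 18.1 ± 4.49 CPM in Em, at least 68.9-fold lower in Eff (adjusted p = 0.184). DDIT3, a stress-response transcription factor gene, had 129 ± 26.5 CPM in Eff and 51.6 ± 10.8 in Em (adjusted p = 0.261). Heat shock genes had a median of 0.02 (adjusted p = 0.0344, and adjusted p = 0.986 with an estimated correlation), a call lost without Em replicate 1, where the direction was reversed (adjusted p = 0.981), Em replicate 2, Eff replicate 2 or Eff replicate 3.

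Other-cell markers differed between Eff and Em too. B cell markers were higher in Eff for all 8 tested members (median 5.05, camera adjusted p = 6.32e-06, and adjusted p = 0.286 with an estimated correlation), with MS4A1 at 1.85 ± 0.610 CPM in Em. Of these members 2 were higher in all 3 donors, donor 1 had a lower mean log2 CPM of the list in Eff than in Em, and the call was lost without donor 3 (adjusted p = 0.0864). Plasma cell markers had a median of 1.86 (adjusted p = 0.00378, and adjusted p = 0.286 with an estimated correlation), a call lost without Eff replicate 2 or Em replicate 3 (adjusted p up to 0.186). Monocyte and macrophage markers were lower in Eff, with a median of -4.23 with absent genes at their bound (adjusted p = 0.00502, and adjusted p = 0.535 with an estimated correlation), CTSD standing at 37.6 ± 19.2 and 169 ± 38.6 CPM. That call was lost without Em replicate 1, Eff replicate 2 or Eff replicate 3 (adjusted p up to 0.257). Fibroblast and endothelial markers had a median of -1.74 at the bound (adjusted p = 0.0460, and adjusted p = 0.286 with an estimated correlation), with ACTA2 at 0 counts in Eff and 9.77 ± 3.81 CPM in Em. The donor block ended that call (adjusted p = 0.109), as did leaving out any 1 of the 9 libraries (adjusted p up to 0.771). Ribosomal protein genes were higher in Eff by a median of 0.19 (adjusted p = 3.18e-10, adjusted p = 0.472 with an estimated correlation and 0.0323 with the donor block besides), and nuclear-retained RNAs had a median of 0.13 and a mean of -0.31 (adjusted p = 0.0140, and adjusted p = 0.226 with an estimated correlation). The last call was lost without Em replicate 1 or Eff replicate 2 (adjusted p up to 0.101).

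**Figure D4:**
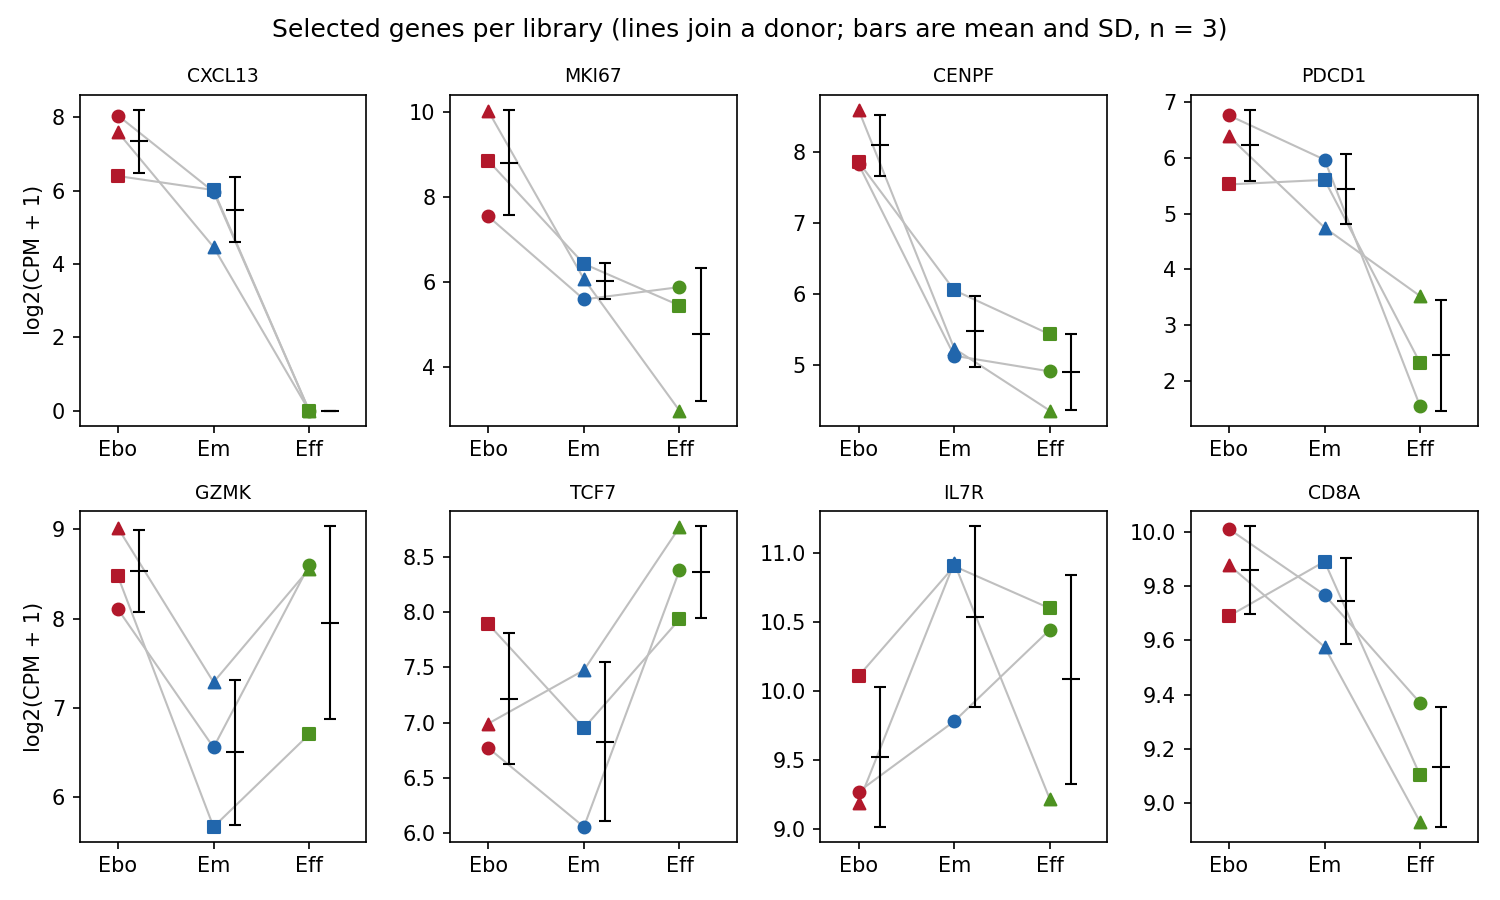
Expression of 8 genes as log2(CPM + 1) in each library, with grey lines joining a donor and bars for the mean and SD of each subset (n = 3). CXCL13 averages 179.97 ± 90.97 CPM (mean ± SD) in Ebo and has 0 counts in Eff, and MKI67 averages 559 ± 433 CPM in Ebo.

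Genes setting Ebo apart from both other subsets were also counted, since the title of the series singles out 1 subset. No gene was called in the same direction in both of Ebo's comparisons, which follows from the 0 calls for Ebo versus Em. DESeq2 gave 79 such genes and 307 with the donor block. At the level of lists, 4 passed in the same direction in both comparisons: cell cycle genes, higher in Ebo, and natural killer markers, NF-kB and immediate-early genes and mitochondrially encoded genes, lower in Ebo. None of the 4 passed with an estimated correlation, and the NF-kB call for Ebo versus Em was lost whichever donor was left out. The 2 comparisons share the Ebo libraries, and how many lists unchanged groups would share was not simulated.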

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

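Thinning to the smallest total, list tests without each donor, the block with an estimated correlation and the 2 groups alone with the block were chosen after the data were examined. Scaling by RLE or upper-quartile factors, a fold of at least 2, removal of mitochondrial, immunoglobulin and haemoglobin genes, and thinning left edgeR's counts at 0, 1 and 1 for Ebo versus Em, Ebo versus Eff and Eff versus Em. Relative to TMM, upper-quartile factors moved the median log2 fold change of all genes by -0.17 for Ebo versus Eff and 0.13 for Eff versus Em, and RLE moved the former by -0.12. With the donor block the counts were 0, 0 and 1, the 1 being MYO7A and not CXCL13. The block ended 3 of 30 list calls and added that of ribosomal protein genes for Ebo versus Em (not with an estimated correlation, adjusted p = 0.248). With an estimated correlation besides, the only calls it kept were those of that list for Ebo versus Eff and Eff versus Em. DESeq2 gave 116, 1363 and 1174 genes with 79 setting Ebo apart from both, DESeq2 with the block 553, 2957 and 2506 with 307, and limma-voom 10, 0 and 0. The cause of these gaps was not tested. In simulated unchanged groups, drawn with the dispersions edgeR had estimated, DESeq2 called up to 173 genes. Without a low-count filter edgeR called 0, 23 and 22 genes, at a mean CPM of at least 10 it called 0, 1 and 0, at an adjusted p under 0.1 it called 0, 10 and 6, and without robust moderation 0, 8 and 1. With the 2 groups alone it called 1 (ASPM, a spindle protein gene chosen after its values were seen), 0 and 0, and with the block besides 0, 0 and 1, where fewer libraries leave fewer degrees of freedom. Leaving out 1 library or 1 donor gave 0 to 137 genes for Ebo versus Eff, 0 to 103 for Eff versus Em and 0 for Ebo versus Em. The highest values came without Eff replicate 2, CXCL13 kept its call for Ebo versus Eff without any 1 library (adjusted p up to 0.0458), and no gene was called without any 1 donor. Of the 30 list calls, 30 held with RLE factors, 29 with thinning, 19 to 28 without 1 library and 21 without any 1 donor. At a mean CPM of at least 10, 23 of 29 with a value held. Fry passed 5 of the 30, the estimated correlation 0, and the block with an estimated correlation 2. Cell cycle genes held without any 1 library or donor (adjusted p up to 6.21e-22 for Ebo versus Em and 9.21e-09 for Ebo versus Eff). The direction was reversed for NF-kB and immediate-early genes, Ebo versus Em, without Ebo replicate 1 (adjusted p = 0.834, and 3.06e-05 without Em replicate 1 to 0.834 over all libraries and donors left out). It was also reversed for monocyte and macrophage markers, Ebo versus Em, without donor 1 (adjusted p = 0.785, range 1.14e-08 without Em replicate 3 to 0.785) and for heat shock genes, Eff versus Em, without Em replicate 1 (adjusted p = 0.981, range 1.23e-06 without Em replicate 3 to 0.981), and the cause was not tested. With this spread edgeR recovered 28 of 66 simulated 64-fold changes in Ebo versus Em, so the counts of called genes set no upper limit on the genes that differ.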

Other observations

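The B cell test and the splits with DESeq2 were chosen after the result they bear on was seen, thinning was added after the data were examined, and the other tests were fixed before their results were seen.

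Lists not yet described did not pass camera in any comparison. For Ebo versus Em the adjusted p was 0.521 for T-cell receptor signalling, 0.989 for cytotoxic granule genes, 0.989 for effector cytokines, 0.464 for activation and costimulation, 0.989 for glycolysis, 0.898 for oxidative phosphorylation and 0.989 for fatty acid oxidation. For Ebo versus Eff the values in the same order were 0.693, 0.989, 0.989, 0.693, 0.574, 0.989 and 0.926, and for Eff versus Em 0.989, 0.989, 0.989, 0.989, 0.584, 0.986 and 0.933. Hypoxia targets gave 0.160, 0.464 and 0.989 for Ebo versus Em, Ebo versus Eff and Eff versus Em. The other process lists, in the same order of comparisons, gave 0.441, 0.106 and 0.393 for anti-apoptotic genes, 0.989, 0.574 and 0.574 for p53 targets, and 0.926, 0.312 and 0.441 for the unfolded protein response. Autophagy genes gave 0.996, 0.203 and 0.183, TGF-beta response genes 0.285, 0.263 and 0.780, and CD4 and regulatory T-cell markers 0.949, 0.226 and 0.302. Markers of epithelial and lung tumour cells gave 0.880, 0.944 and 0.949. Dendritic cell and neutrophil markers had 2 tested members each and mast cell, red cell and platelet markers 0, so these lists were not tested.

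Within the mitochondrial genome the Eff library of donor 1 stood apart. It had 16 counts of MT-ND4 and 379 of MT-ND2, at 1.53 and 36.4 CPM, and 0 of MT-ND3, while MT-ND5 had 106044 counts and MT-CYB 50545. The other 8 libraries had a median of 12431 CPM for MT-ND4 and 4923.4 CPM for MT-ND2. MT-ND3 was also at 0 counts in the Eff library of donor 3. These genes were singled out after their values were seen, and no explanation was tested.

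Cell cycle genes were higher in Ebo than in both other subsets. Depth as the whole cause is argued against, since with all libraries thinned to the smallest total the larger adjusted p of the list in the 2 comparisons was 1.69e-20. A general loss of moderately abundant transcripts outside Ebo is also argued against, since the list medians of 2.32 and 6.66 lay above all 10000 random lists matched on mean expression (percentile 100 in both), whose highest medians were 0.53 and 2.31. Whether cycling cells of another type entered the Ebo sort was not tested and stays open. Fibroblast and endothelial markers took a larger share of counts in every Ebo library than in any other, at 0.0288% on average in Ebo, 0.0169% in Em and 0.0205% in Eff. The list of those markers passed in neither comparison, with a median of -0.18 for Ebo versus Em and 2.53 for Ebo versus Eff (adjusted p = 0.895 and 0.0888), and the sort asked for CD45 and CD8. Monocyte and macrophage markers took 0.0276% in Ebo and 0.0134% in Eff without overlap, but 0.0469% in Em. The exact permutation p was 0.1 and the adjusted p 0.33 for the 2 fibroblast and endothelial differences and for the monocyte difference between Ebo and Eff. A larger share of dividing T cells in Ebo also stays open and was not tested, and 3 donors leave chance open.

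Fewer genes were detected in Eff than in Ebo, by 5787 genes on average. After thinning 91.9% of that gap was left, and after leaving out each library's 50 most abundant genes and thinning 91.0% was left, which argues against depth and against a few dominant genes as the whole cause. Random loss of transcripts in each library, as few sorted cells could give, stays open: 1313 genes detected in every Ebo library were missing from all 3 Eff libraries, 1.73 times the 757 expected from independent loss, between the bounds set for and against it. A narrower transcriptome of Eff cells likewise remains open, and the sorted cell number, which the labels put lower for Eff than for Em, cannot be told apart from the subset.

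B cell markers were higher in Eff than in Em, although the sort asked for CD8. If B cells had entered the Eff sort of each donor, over 50% of the 13 markers would be higher in Eff in 3 donors, and this was seen in 2 donors, with 8 and 11 markers, against 2 markers in donor 1. Among the tested markers the highest means were 112 ± 169.7 CPM for BANK1 and 63.95 ± 68.4 CPM for MS4A1 in Eff, against 565 ± 88.1 for CD8A. These means rest largely on donor 3, whose Eff library had 308 CPM of BANK1, 141 of MS4A1 and 486 of CD8A. B cells in some sorts, bound to T cells or not, may account for the higher markers, and expression by the T cells themselves cannot be told apart from that.

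Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. For genes called by edgeR, the real split gave 0, 1 and 1 for Ebo versus Em, Ebo versus Eff and Eff versus Em, the highest other split 0, 0 and 1, and 10, 1 and 3 splits gave as many. For lists called, p was adjusted here within 1 comparison and not over the 3 together, so the counts can differ from those in the main test. The real split gave 5, 13 and 11 lists, the highest other 14, 15 and 13, and 8, 3 and 2 splits gave as many. Among the 4 splits that part all 3 donors, the real one included, the highest other gave 5, 8 and 10 lists, so the higher counts came from splits that set donors against each other. For the cell cycle list the real p was 2.16e-41 for Ebo versus Em and 6.04e-22 for Ebo versus Eff, and the lowest other 3.08e-13 and 3.35e-08. DESeq2 was run on the same splits with the third group kept in the fit, over the 14794 genes tested in edgeR only. It gave 69, 930 and 792 genes for the real splits and at most 88, 142 and 788 for the others.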
